A study of Mus musculus with 4 samples.

How the data were processed

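The data were 4 single-cell RNA libraries from mouse lungs, 1 library for each combination of tumour genotype and antibody. Lung cancer cells of the KP mouse model were injected into the blood of B6 mice, where they form lung tumours, per the labels. The tumour cells were either wild type for the histone chaperone gene Asf1a (WT) or knocked out for it (KO). The mice received a control IgG or an antibody against PD-1, the inhibitory receptor on T cells, at 200 µg per mouse, 3 doses per week, for 1 week, per the labels. Whole lungs were digested with collagenase D, live cells were sorted by DAPI staining, and libraries were made with the 10x Genomics 3′ v2 kit, per the labels. The groups are called WT IgG, WT anti-PD-1, KO IgG and KO anti-PD-1 below.

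The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell, written as whole numbers by Cell Ranger 3.0.0, per the file headers. The submitters' processing notes name bcl2fastq and Cell Ranger and give the genome build as hg19, a human build, while all 31053 gene identifiers in the deposited feature table are mouse Ensembl identifiers. The build that was used is therefore not established, and no coordinates are given here. The deposited matrices hold barcodes that had already been called as cells, the lowest with 500 UMIs in every library. They were otherwise not normalised, judged from whole numbers and unequal totals.

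Cells with fewer than 200 detected genes or more than 10% mitochondrial UMIs were removed, which took out 9 and 320 cells of WT IgG, 13 and 385 of WT anti-PD-1, 15 and 324 of KO IgG, and 19 and 398 of KO anti-PD-1. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5, with an expected rate of 0.05. The automatic threshold called 95, 125, 7 and 6 doublets in the order above, so a fixed score limit of 0.25 was set after these values were seen. It removed 86, 98, 104 and 82 cells. The cells kept numbered 5659, 6187, 5919 and 5595, with median depths of 2026, 1881, 1220 and 1339 UMIs.

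Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen across the libraries. From these, 30 principal components and 15 neighbours entered Leiden clustering at resolution 1 (igraph 0.11.9), which gave 23 clusters. No batch correction was made. A cluster was scored against each of 32 marker lists by the mean log2 ratio of its CPM, with 10 added, to that of cells outside its provisional class. It took the class of the best list if the score was at least 1, exceeded that of any other class by 0.5 and had at least 3 markers detected in 10% of cells. It stayed unnamed if its 10 leading genes held more markers of another class, or if its cells held few UMIs and no marker of its own led. The tumour group and the T cell group were clustered again and each sub-cluster was named against the cells outside the group. T sub-clusters that kept the T cell class were then scored by the same rule against the other T cells on 5 subset lists (CD8, CD4, regulatory, naive and gamma-delta T cells). Sub-clusters 5 and 9 took the CD8 name (scores 1.95 and 1.15) and are called CD8-named T cells, and sub-cluster 2 took the CD4 name. Sub-clusters 0, 10 and 11, with Cd8a and Cd8b1 among their 10 leading genes against cells outside the group, scored under 1 on every subset list and held 268, 27 and 17 cells of WT IgG and 259, 18 and 5 of KO IgG.

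The marker lists were fixed before the data were examined, but the naming rule was not. It was written after a first clustering had been looked at with cell numbers per library in view, and 3 versions were run. The first version scored each cluster against all other cells. The second scored tumour and T cell sub-clusters against cells outside their group, since sub-clusters had diluted each other. The last, used for all results, did so for every cluster in 2 passes, because a large Siglecf-high neutrophil cluster had gone unnamed under the 5% mitochondrial limit. It also left a cluster unnamed whenever another class came within 0.5, which set aside T cells that carried DC genes. The earlier versions were not kept as alternatives, so the shares were not computed under them.

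Clusters 5 and 10 were macrophage-like and cluster 9 monocyte-like, and these formed 1 class, here called monocytes and macrophages. Alveolar macrophages were kept apart. Within the tumour class, sub-cluster 0 held 19, 17, 4 and 10 cells of the 4 libraries in the order above, sub-cluster 7 held 4, 13, 34 and 16, and sub-cluster 9 held 3, 7, 53 and 23. Unnamed cells were 12, 13, 12 and 27, or 0.212%, 0.210%, 0.203% and 0.483% of the cells.

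The share of each class in each library was given with an exact Clopper-Pearson 95% interval. For expression, UMIs were summed per class and library and written as CPM, the count per 1e+06 UMIs of the class, for classes with at least 50 cells in each library. Ratios of 2 libraries carry exact conditional 95% intervals of 2 Poisson sums. Genes with at least 50 UMIs in the 2 libraries together were counted when at least 2-fold apart in CPM. For a gene with 0 UMIs in 1 library, the fold was computed against a floor of 3 UMIs in that library and is a lower bound. Of each fixed gene list, members with at least 20 UMIs entered the median log2 ratio. That median was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, and its interval came from 1000 Poisson draws of the counts. Members at least 1.5-fold higher or lower were counted. The comparisons were KO IgG, WT anti-PD-1 and KO anti-PD-1, each against WT IgG, and KO anti-PD-1 against WT anti-PD-1 and against KO IgG, with the difference of the 2 antibody effects. With 1 library per group, no test was made and no p-value is given. All intervals cover counting error only and say nothing of the spread between mice.

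The 21 gene lists, the comparisons, the rule for named genes and the first group of alternatives given below were likewise fixed before the data were examined. The lists were M1-type and M2-type macrophage genes, interferon-gamma response, type I interferon response, MHC class I and class II presentation, NF-kB and TNF inflammatory genes, chemokines, cytotoxic effectors, T cell activation, T cell inhibitory receptors, naive and memory T cell genes, regulatory T cell genes, proliferation, histone chaperones, hypoxia and glycolysis, dissociation and heat-shock stress, colony-stimulating factors, checkpoint ligands, epithelial-mesenchymal transition, and suppressive neutrophil genes. Genes were named by rule. For each class and comparison against WT IgG these were up to 5 genes with the largest and 5 with the smallest ratio. They had to be at least 2-fold apart and have a CPM in the class of at least 0.25 of their highest in any class, as a guard against RNA free in the suspension. Mitochondrial, ribosomal, immunoglobulin, T cell receptor and sex-linked marker genes and genes with Gm or Rik names were left out of that ranking. Of each list, 2 to 4 members with the largest ratios were named, and a fixed set that included Asf1a, Csf2, Cd274, Pdcd1, Arg1, Cxcl9, Ifng and Gzmb was always looked at. Not every gene of that set is reported here.

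The steps from class sums onward were tested on counts simulated from the sums of the KO IgG and WT IgG libraries, with 200 genes changed by known folds. Clustering and naming were not part of that test. Spread between single cells or between mice was not part of it either, since the counts were simulated from sums. In monocytes and macrophages (8464 genes), 94% of genes raised 2.5-fold, 96% of those lowered to 0.4 and 100% of those at 4 or 0.25 passed the 2-fold limit, as did 0.157% of unchanged genes. In T cells (7735 genes) these were 96%, 88% and 100%, with 0.372% of unchanged genes. These rates cover counting error only. They give no false rate for the gene counts reported below, where the UMIs of a gene can lie in few cells. A list raised 2.5-fold stood at percentile 100 in both classes, and unchanged lists stood at 36.1 and 93.9.

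Alternatives were 500 detected genes, 5% or 20% mitochondrial UMIs, doublets kept, Leiden resolution 0.5 or 2, immune cells as denominator, TMM size factors (edgeR 4.0.16 in R 4.3.3) or median-of-ratios size factors, a mean of each cell's CPM, other UMI minimums, cells thinned to 1000 UMIs, and the free-RNA guard applied to all genes. Chosen after the data were seen were 700 and 1000 UMIs per cell, each library thinned by 1 fraction, a CD8 group of all T sub-clusters led by Cd8a and Cd8b1 (CD8-led cells), a denominator without neutrophils, macrophage-like and monocyte-like clusters apart, ratios less the median of all genes, and ratios without the cell holding the most UMIs of the gene in each library. The fractions kept were 64.1%, 69.9%, 90.4% and 100%, the median over classes other than neutrophils of the depth of KO anti-PD-1 over that of the library, so single classes were not matched. For a test of depth, cells of the tumour class and of monocytes and macrophages were also thinned to 3000 and to 5000 UMIs. Classes under 50 cells in any library (alveolar macrophages, plasmacytoid DCs, naive, CD4 and gamma-delta T cells, endothelial cells, fibroblasts and basophils) entered the shares only. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and Matplotlib 3.10.9. A barcode list covering 1 library was not used here, since cells were taken by their column.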

Results

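Single-cell RNA counts were collected from the whole lungs of mice bearing KP tumours, in 4 libraries, 1 per group. The tumours were WT or KO for Asf1a, and the mice received control IgG or anti-PD-1. The libraries held 22506737 UMIs (WT IgG), 22369904 (WT anti-PD-1), 17578188 (KO IgG) and 16078095 (KO anti-PD-1), and 5659, 6187, 5919 and 5595 cells were kept. There were no replicates, so nothing below measures the spread between mice, and every difference is one between single libraries. Intervals are 95% and cover counting error only. The KO libraries were shallower. The median depth of T cells was 2442.5, 2059.5, 1629 and 1598 UMIs in the order above, and that of neutrophils was 1258.5, 1130.5, 893 and 771.

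Asf1a, the targeted gene (ENSMUSG00000019857), encodes a chaperone that hands histones H3 and H4 to the chromatin assembly machinery. In tumour cells its level was 34.2 CPM (26.5 to 43.4, 67 UMIs) in WT IgG and 30.0 CPM (22.6 to 39.0, 55 UMIs) in WT anti-PD-1. It was 9.77 CPM (6.49 to 14.1, 28 UMIs) in KO IgG and 7.66 CPM (4.29 to 12.6, 15 UMIs) in KO anti-PD-1. Both KO libraries together stood at 0.277 (0.191 to 0.395) of both WT libraries. In all other cells the ratio was 0.972 (0.864 to 1.09), with 18.2, 18.2, 18.7 and 16.6 CPM. The counts are 3′ tags, which an edited gene can still yield, and the position of the guide is not given in the sources used here. Tumour cells numbered 114, 116, 222 and 139, so tumour values rest on few cells.

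The question of the first comparison, KO IgG against WT IgG, is what loss of Asf1a in the tumour cells goes with in the untreated lung. Neutrophils are short-lived phagocytes that gather in inflamed and tumour-bearing tissue. T cells recognise antigens, and their CD8 subset kills target cells. Interferon gamma, made by T and NK cells, switches on antigen presentation genes in tumour cells and macrophages. Shares refer to live cells by DAPI sort that held at least 500 UMIs, and shallow libraries lose cells with little RNA at that minimum. CD8-named T cells below are the T sub-clusters 5 and 9, while CD8-led cells also include sub-clusters 0, 10 and 11, which Cd8a and Cd8b1 led but no subset list named.

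Neutrophils made up 33.1% (31.9 to 34.4) of cells in WT IgG and 46.6% (45.4 to 47.9) in KO IgG, a ratio of 1.41 (1.33 to 1.49). This direction turned with the minimum depth, since the ratio was 0.825 with at least 500 detected genes and 0.866 with at least 1000 UMIs per cell. These minimums were not scaled to the unequal depth of the libraries. With a minimum scaled to depth (1000 UMIs in WT IgG) the ratio was 1.43 (1.34 to 1.53), but that removed too few cells to bring it to 1. Tumour cells were 2.01% and 3.75%, a ratio of 1.86 (1.48 to 2.35). T cells were 29.6% (28.4 to 30.8) and 16.7% (15.7 to 17.6), a ratio of 0.564 (0.521 to 0.610). CD8-named T cells stood at 0.385 (0.305 to 0.485) of their WT IgG share and all CD8-led cells at 0.645 (0.566 to 0.735), regulatory T cells at 0.585 (0.441 to 0.771) and B cells at 0.567 (0.481 to 0.666). Within T cells the CD8-named subset was 15.7% and 10.7%, but all CD8-led cells were 34.3% and 39.3%, which turned the direction. Regulatory T cells were 8.30% and 8.61% of T cells. Monocytes and macrophages were 12.9% and 14.7%, a ratio of 1.14 (1.03 to 1.26), and NK cells were 5.11% and 4.88%.

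**Figure D1:**
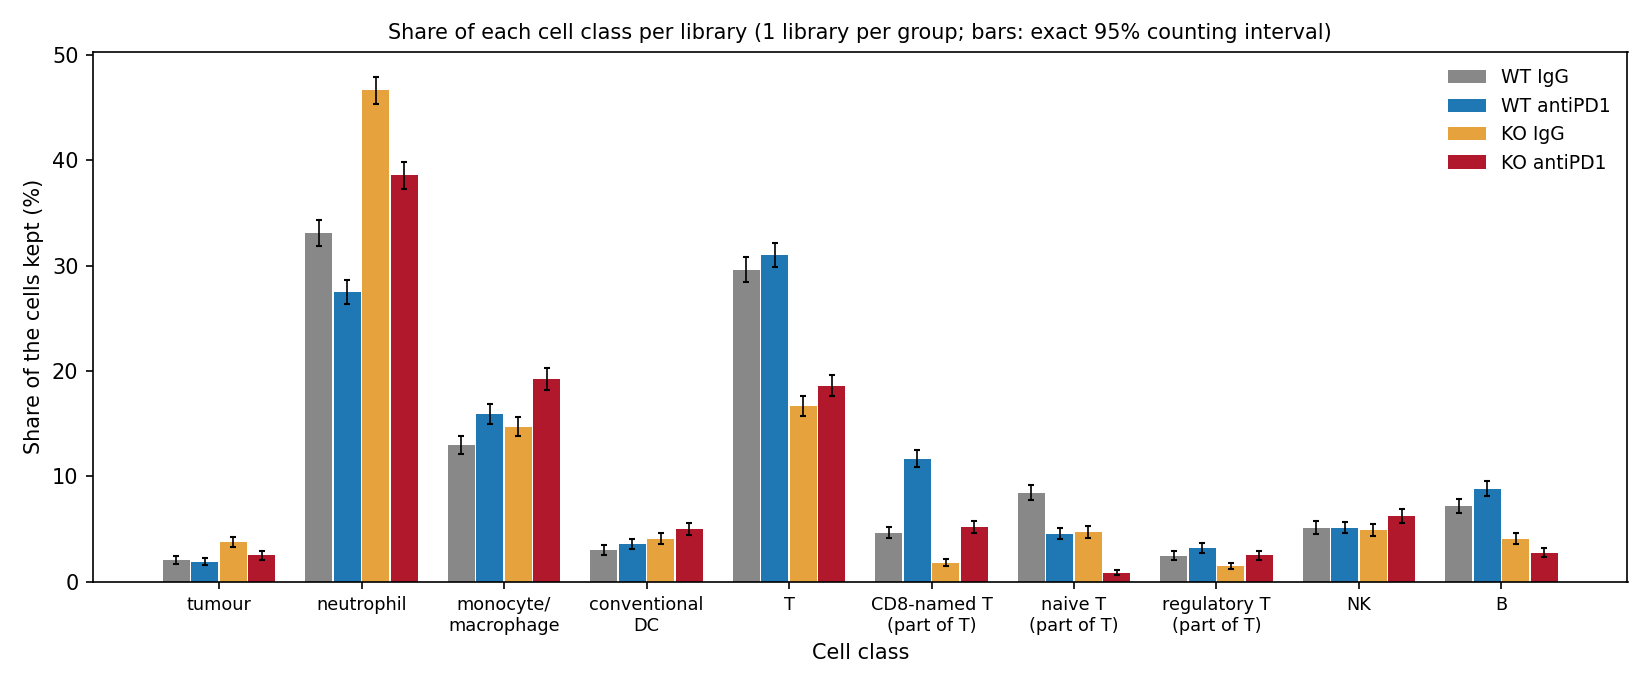
Share of each cell class (percent of cells kept, vertical axis from 0) in the 4 libraries, with exact 95% Clopper-Pearson intervals as error bars. Neutrophils were 33.1% of cells in WT IgG and 46.6% in KO IgG, and T cells were 29.6% and 16.7%.

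Tumour cells of KO IgG had lower interferon-gamma response genes than those of WT IgG. The median log2 ratio over 14 members was −0.97 (−1.24 to −0.74), with 11 at least 1.5-fold lower and none higher, below all random lists. The proteasome subunit Psmb9 was at −2.55, the GTPase Iigp1 at −1.69 and the signalling inhibitor Socs1 at −1.26. MHC class I genes had a median of −0.91 (−1.11 to −0.68) over 13 members, with the peptide transporter Tap2 at −2.40 and the MHC heavy chains H2-K1 at −1.89 and H2-D1 at −1.12. Type I interferon genes stood at −0.85 (−1.20 to −0.53), with Isg15 at −2.12. Proliferation genes were higher, at 0.55 (0.44 to 0.73) over 24 members, with the mitotic kinase Aurkb at 1.74. Immediate-early and heat-shock genes, which tissue digestion can induce, stood at −0.82 (−1.004 to −0.72), with Fosb at −1.81 and Fos at −1.76. Across the classes of KO IgG where it was measured, Hspa1a of that list was higher in 4 of 5 and lower in 1.

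The other lists in tumour cells had smaller medians. Chemokines stood at −0.53 (−0.78 to −0.38), hypoxia and glycolysis at −0.20 (−0.36 to −0.13), and checkpoint ligands at −0.42 (−0.60 to −0.09). Epithelial-mesenchymal genes stood at 0.03 (−0.14 to 0.12) and histone chaperones at 0.12 (−0.19 to 0.31), the latter with Chaf1a at 2.10 and the paralogue Asf1b at 1.28. Colony-stimulating factors had a median of −0.05 (−0.58 to 0.54) over 6 members. Among these Csf2, which encodes the myeloid growth factor GM-CSF, was at 1.91 (0.64 to 3.46) on 33 UMIs from 8 cells against 6 UMIs.

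By size, 281 genes were at least 2-fold higher and 376 lower in KO IgG tumour cells among 7285. These are counts of ratios and not of tested changes. Among the genes named by rule, S100a4, a calcium-binding protein linked to cell motility, was 7.72-fold higher (683 and 7707 UMIs). Akr1c18, a steroid dehydrogenase, was 35.7-fold higher on 209 against 4 UMIs. Lgals4, an intestinal-type galectin, was 58.1-fold lower (1510 and 38 UMIs), and Gkn2, a stomach-type secreted protein, was at least 73.6-fold lower on 0 against 151 UMIs. The tumour sub-clusters differed between the libraries. Sub-cluster 0 held 19 of the WT IgG and 4 of the KO IgG cells, while sub-clusters 7 and 9 held 4 and 3 against 34 and 53. All 267 UMIs of Cxcl13 in WT IgG tumour cells came from 1 cell.

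In monocytes and macrophages of KO IgG, interferon-gamma genes had a median of −0.64 (−0.76 to −0.53) over 22 members, with 13 lower and none higher, and type I interferon genes stood at −0.70 (−0.92 to −0.56). M1-type genes, which mark inflammatory macrophages, stood at −0.38 (−0.49 to −0.29) and M2-type genes at −0.03 (−0.13 to 0.05). The chemokine gene Ccl8 was 11.5-fold lower (848 and 64 UMIs), and Mmp12, a macrophage elastase, was 2.96-fold higher. Arg1, which depletes arginine, was at −0.67 (−0.73 to −0.60). Tnf was at 1.21, but at −0.02 without the cell holding the most of its UMIs in each library. MHC class I genes stood at −0.26, class II at −0.01, NF-kB and TNF genes at −0.12 and chemokines at 0.02. By size, 45 genes were higher and 54 lower among 8490.

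In T cells of KO IgG, cytotoxic genes had a median of −0.26 (−0.43 to −0.04), and Ifng itself was at −2.16 (−2.82 to −1.55) on 24 against 277 UMIs. Gzmb was at −0.99 and Gzma at −1.26, with 23.8% of the 961 Gzma UMIs of WT IgG in 1 cell. Inhibitory receptors stood at −0.31 (−0.52 to −0.09), proliferation genes at −0.41 (−0.58 to −0.33) and naive and memory genes at 0.20 (0.11 to 0.30). T cell medians also carry the mix of sub-clusters. Sub-cluster 8, led by Top2a, held 4.48% of T cells in WT IgG and 1.72% in KO IgG. Sub-cluster 0 held 16.0% and 26.2%, while naive T cells were 28.4% and 28.1%. Regulatory genes stood at 0.10 and activation genes at 0.05. By size 48 genes were higher and 57 lower, but 26 and 81 with TMM factors and 31 and 77 with median-of-ratios factors. In NK cells the cytotoxic median was 0.02 (−0.16 to 0.08). In neutrophils the suppressive list stood at 0.05 (−0.04 to 0.16), within which Wfdc17 was at 2.39 (28830 and 5302 UMIs), and Cxcl10 was 4.68-fold lower. These values also carry the mix of neutrophil clusters, since cluster 3 held 47.6% of neutrophils in WT IgG and 36.5% in KO IgG, and cluster 1 held 18.2% and 28.9%. Neutrophil genes past 2-fold were 36 higher and 67 lower, or 52 and 53 with TMM factors and 54 and 51 with median-of-ratios factors. Haemoglobin genes led the neutrophil ranking from 7 to 12 cells.

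The comparison of WT anti-PD-1 with WT IgG asks what PD-1 blockade goes with in lungs bearing WT tumours. PD-1, encoded by Pdcd1, restrains T cells that have met antigen, and antibodies against it release that restraint. Granzymes and perforin carry out killing by T and NK cells. Cxcl9 and Cxcl10 encode chemokines that draw activated T cells and are induced by interferon gamma. These libraries were closer in depth than those of the other comparisons against WT IgG.

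CD8-named T cells were 4.65% of cells in WT IgG and 11.7% in WT anti-PD-1, a ratio of 2.51 (2.18 to 2.90), while all T cells were 29.6% and 31.0%. Within T cells that subset was 15.7% and 37.6%, a ratio of 2.40 (2.08 to 2.77). For all CD8-led cells these ratios were 1.59 (1.44 to 1.77) and 1.52 (1.37 to 1.69). Naive T cells were at 0.540 (0.464 to 0.627) of their share and regulatory T cells at 1.30 (1.04 to 1.62). That interval reached 1 under several settings, with 1.17 (0.890 to 1.55) for at least 500 detected genes and 1.08 (0.787 to 1.49) for at least 1000 UMIs. Neutrophils were at 0.830 (0.777 to 0.887), monocytes and macrophages at 1.23 (1.12 to 1.35) and tumour cells at 0.931 (0.712 to 1.22).

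T cells of WT anti-PD-1 had a cytotoxic median of 0.50 (0.38 to 0.63) over 17 members, with Ccl5 at 1.44, Gzmk at 1.33 and Gzmb at 1.31. Inhibitory receptors stood at 0.70 (0.57 to 0.86), with Havcr2 at 1.29, Lag3 at 1.12 and Pdcd1 at 0.97. Naive and memory genes stood at −0.44 (−0.50 to −0.33), regulatory genes at 0.26 (0.14 to 0.37), activation genes at 0.11 and proliferation genes at 0.08. The median of all genes lay at 0.11 in this comparison. By size 54 genes were higher and 16 lower, or 37 and 25 under both other scalings. Within CD8-named T cells alone the cytotoxic median was 0.13 (0.01 to 0.29). In NK cells it was 0.32 (0.23 to 0.48), with the receptor Cx3cr1 4.01-fold higher.

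Tumour cells of WT anti-PD-1 had an interferon-gamma median of 1.17 (0.86 to 1.55) over 19 members, with 14 higher and none lower, led by Cxcl9 at 5.49 and Ido1, which depletes tryptophan, at 2.87. This size depended on the weighting of cells, being 0.27 as a mean over cells of each cell's CPM and 0.10 with each cell thinned to 1000 UMIs. A single cell held 51.6% of the 126 Cxcl9 UMIs. MHC class I genes stood at 0.44 (0.26 to 0.69), type I interferon genes at 0.68 (0.27 to 0.94) and proliferation genes at 0.29 (0.19 to 0.39). Hypoxia and glycolysis genes stood at −0.37 (−0.49 to −0.30). By size 51 genes were higher and 101 lower among 6450. These counts were 303 and 367 as a mean over cells, and 6 and 5 with each cell thinned to 1000 UMIs.

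Monocytes and macrophages of WT anti-PD-1 had an interferon-gamma median of 0.71 (0.60 to 0.81), with 15 members higher and none lower, among them Cxcl9 at 1.71 and Gbp5 at 1.23. The macrophage-like clusters alone stood at 1.02 and the monocyte-like cluster alone at 0.07. M1-type genes stood at 0.28 (0.16 to 0.57), with Nos2, the inducible nitric oxide synthase, at 3.61. Nos2 was at 2.94 without the cell holding the most of its UMIs in each library, which in WT anti-PD-1 held 58.1%. In the monocyte-like cluster alone that list stood at −0.01. M2-type genes stood at −0.21 (−0.31 to −0.09), with Arg1 at −0.79 (−0.85 to −0.73). Class values also carry the mix of clusters. The monocyte-like cluster 9 held 41.3% of the class in WT IgG and 51.5% in WT anti-PD-1, and cluster 10, led by Arg1, held 35.8% and 29.8%. MHC class II genes stood at 0.29, and chemokines at −0.21. By size 47 genes were higher and 34 lower.

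The comparison of KO anti-PD-1 with WT IgG asks what both changes together go with, and its ratios to WT anti-PD-1 and KO IgG separate the parts. A response to blockade would be read from effector T cells and interferon targets. Loss of naive T cells, which recirculate through blood and lymphoid tissue, changes the make-up of the T cell class. In KO anti-PD-1, the library with the fewest UMIs in all, 78.3% of neutrophils held under 1000 UMIs against 21.0% in WT IgG.

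Monocytes and macrophages were 12.9% (12.1 to 13.8) of cells in WT IgG and 19.2% (18.2 to 20.3) in KO anti-PD-1, a ratio of 1.49 (1.35 to 1.64). It was 2.06 with at least 500 detected genes. The monocyte-like cluster was at 1.88 (1.63 to 2.16). T cells were at 0.629 (0.582 to 0.680) and B cells at 0.377 (0.311 to 0.456). CD8-named T cells were 5.17% of cells, or 1.11 (0.937 to 1.32) of the WT IgG share, 2.88 (2.30 to 3.64) of the KO IgG share and 0.443 (0.385 to 0.508) of the WT anti-PD-1 share. For all CD8-led cells these were 0.862 (0.763 to 0.974), 1.34 (1.17 to 1.53) and 0.541 (0.484 to 0.603). Naive T cells were 8.41% and 0.804%, a ratio of 0.0956 (0.0688 to 0.130). Neutrophils were at 1.16 (1.09 to 1.24), but at 0.472 with at least 500 detected genes, 0.902 with at least 700 UMIs and 0.460 with at least 1000 UMIs. With the minimum scaled to depth, they were 29.4% (28.1 to 30.7) of cells in WT IgG and 32.8% (31.5 to 34.1) in KO anti-PD-1. Tumour cells were at 1.23 (0.956 to 1.59) against WT IgG and 0.662 (0.532 to 0.822) against KO IgG. The regulatory T cell ratio to WT anti-PD-1 was 0.780 (0.623 to 0.974), but its interval included 1 under each other cell filter, clustering resolution and depth setting tried. It turned to 1.15 with at least 500 detected genes and 1.10 with each library thinned by 1 fraction. Within T cells the direction also turned, to 1.30 (1.04 to 1.62) of the WT anti-PD-1 share. Against WT IgG the ratio within T cells was 1.61 (1.26 to 2.05).

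**Figure D2:**
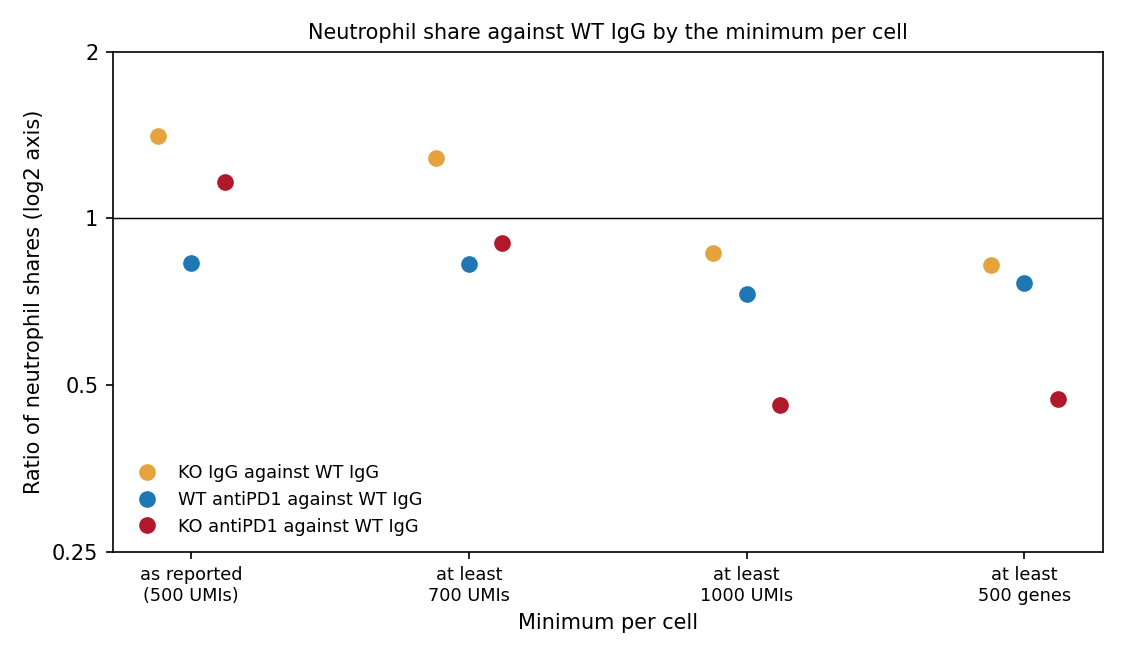
Ratio of each library's neutrophil share to that of WT IgG (log2 axis, 1 point per library) by the minimum a cell had to reach. The KO IgG point lies at 1.41 as reported, 0.866 with at least 1000 UMIs per cell and 0.825 with at least 500 detected genes. The minimums shown were not scaled to the depth of each library.

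Tumour cells of KO anti-PD-1 had an interferon-gamma median of 1.30 (0.89 to 1.55) against WT IgG, with 14 members higher and 1 lower. Against KO IgG it was 2.13 (1.72 to 2.49), with 16 of 17 members higher. Against WT anti-PD-1 it was −0.17 (−0.37 to −0.01). As a mean over cells the value against WT IgG was 0.33. MHC class I genes stood at 0.36 (0.17 to 0.52), which turned to −0.17 as a mean over cells and −0.50 under the guard against free RNA. Type I interferon genes stood at 1.01 (0.77 to 1.33), and Ifit3 was 36.2-fold higher from 10 cells. Proliferation genes stood at 1.14 (0.89 to 1.21), with 20 of 24 members higher. Csf2 was at 1.81 (0.45 to 3.41) and Cd274, the PD-1 ligand, at 1.07 (−0.08 to 2.32). By size 212 genes were higher and 359 lower among 6530. Lypd8, an intestinal surface protein, was at least 600-fold higher on 1799 UMIs, all from 7 cells.

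In T cells of KO anti-PD-1 the cytotoxic median was 0.61 (0.50 to 0.77) against WT IgG, 0.88 (0.64 to 1.13) against KO IgG and 0.00 (−0.04 to 0.14) against WT anti-PD-1. Gzmb was at 1.39 and Gzma at 1.22 against WT IgG, with 27.4% of the 944 Gzma UMIs of KO anti-PD-1 in 1 cell. Inhibitory receptors stood at 0.77 (0.49 to 0.96), regulatory genes at 0.76 (0.55 to 0.90), with Il10 at 2.46 (1.80 to 3.16), and proliferation genes at 0.36 (0.23 to 0.43). The regulatory median also carries the mix of T cells, since regulatory T cells were 8.30% of them in WT IgG and 13.4% in KO anti-PD-1. Naive and memory genes stood at −0.93 (−1.02 to −0.77), with Lef1 at −1.13, and activation genes at 0.33. Within CD8-named T cells the cytotoxic median was 0.13 (−0.02 to 0.37), with Ifng at −1.60. The median of all genes in T cells lay at 0.12. By size 117 genes were higher and 96 lower, but 61 and 165 with TMM factors and 70 and 151 with median-of-ratios factors.

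In monocytes and macrophages of KO anti-PD-1 the interferon-gamma median was 0.23 (0.16 to 0.32) against WT IgG, 0.89 (0.76 to 0.99) against KO IgG and −0.37 (−0.55 to −0.32) against WT anti-PD-1. Against WT IgG the macrophage-like clusters stood at 0.38 and the monocyte-like cluster at −0.17. M1-type genes stood at −0.03 (−0.16 to 0.07) and M2-type genes at −0.20 (−0.39 to 0.01). Arg1 was at −1.07 (−1.14 to −1.003), the mannose receptor Mrc1 at −0.79 and Cd274 at −0.36 (−0.63 to −0.09). The mix of clusters differed here too, with 52.0% of the class in cluster 9 and 28.2% in cluster 10, against 41.3% and 35.8% in WT IgG. By size 58 genes were higher and 113 lower among 8487. In neutrophils the suppressive list stood at 0.12 (0.00 to 0.22), with Wfdc17 4.46-fold higher, and 99 genes were higher and 114 lower. Cluster 3 held 33.0% and cluster 1 31.3% of neutrophils in that library.

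**Figure D3:**
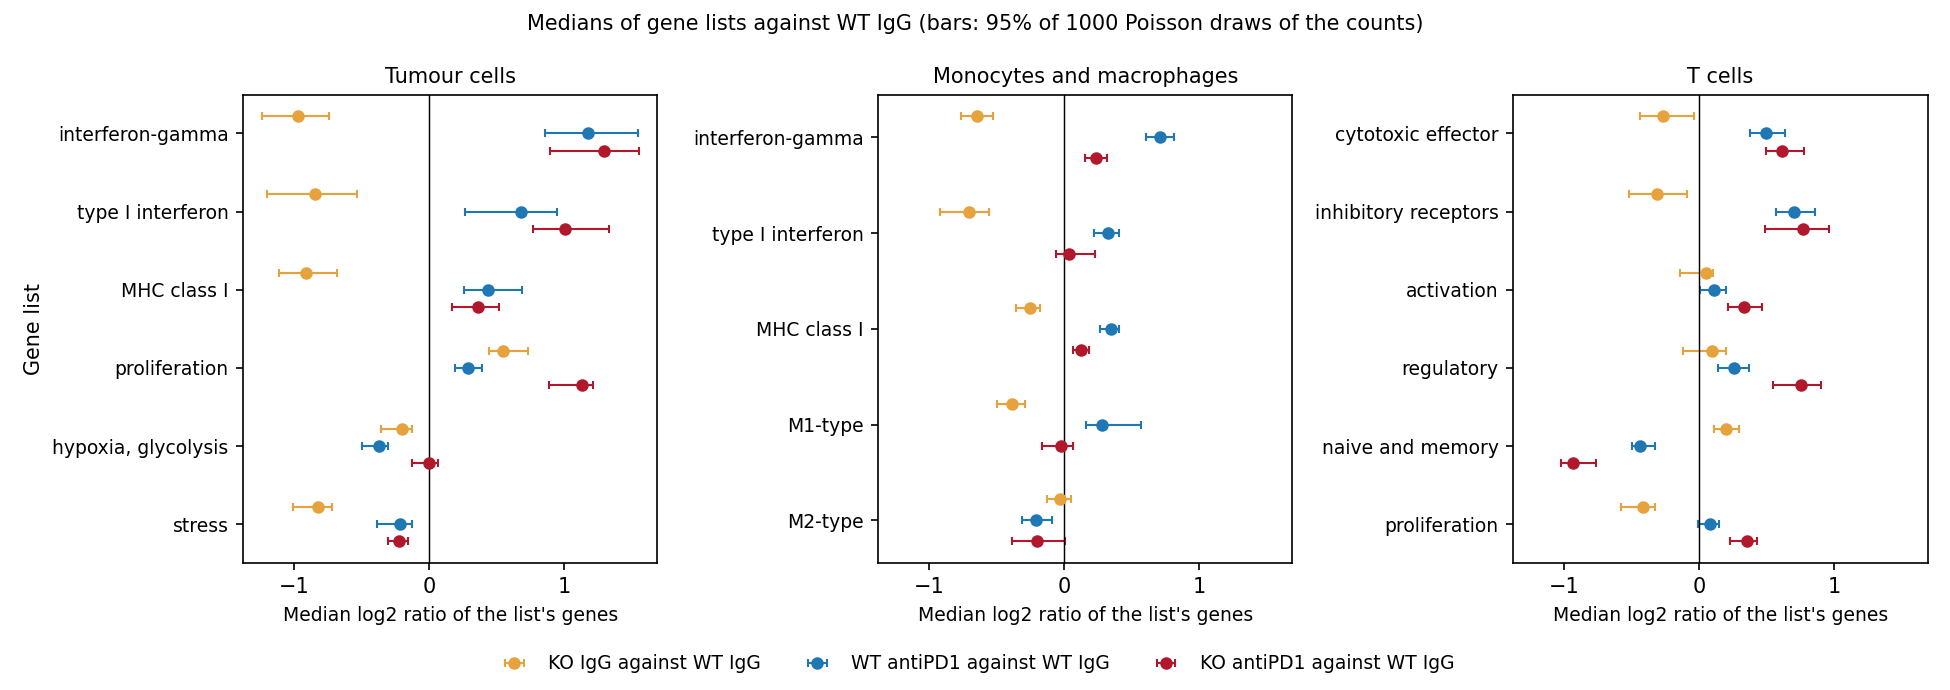
Median log2 ratio of gene lists in tumour cells, monocytes and macrophages, and T cells, for each library against WT IgG, with 95% intervals from Poisson draws of the counts. The interferon-gamma median of tumour cells was −0.97 in KO IgG, 1.17 in WT anti-PD-1 and 1.30 in KO anti-PD-1.

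The layout also gives the antibody effect in KO tumours less that in WT tumours. On the log2 scale of shares this was 0.20 (−0.18 to 0.58) for CD8-named T cells, −0.25 (−0.50 to −0.01) for all CD8-led cells, −0.01 (−0.13 to 0.12) for neutrophils and 0.09 (−0.10 to 0.28) for monocytes and macrophages. It was −1.65 (−2.15 to −1.15) for naive T cells and −0.49 (−0.97 to −0.01) for tumour cells, the latter −0.37 (−0.86 to 0.13) with at least 700 UMIs and −0.40 (−0.93 to 0.13) at clustering resolution 2. It was 1.99 (1.29 to 2.70) for CD4-named T cells, which are sub-cluster 2 alone, but 0.89 (0.47 to 1.31) with at most 5% mitochondrial UMIs, where that name covered more cells. For plasmacytoid DCs it was 1.25 (0.36 to 2.14). The neutrophil value depended on the minimum per cell. With at least 1000 UMIs the neutrophil shares against WT IgG were 0.730 in WT anti-PD-1, 0.866 in KO IgG and 0.460 in KO anti-PD-1. There the fall with anti-PD-1 was larger in KO than in WT tumours. That minimum was not scaled to depth. It removed 21.0% of neutrophils in WT IgG, 34.3% in WT anti-PD-1, 66.0% in KO IgG and 78.3% in KO anti-PD-1. With a minimum scaled to the depth of each library (1000 UMIs in WT IgG), the shares were 29.4%, 23.9%, 42.1% and 32.8% in that order. Over list members the median difference in tumour cells was 0.92 for interferon-gamma genes and 0.68 for MHC class I genes. Among the other lists it was 1.28 for type I interferon genes and −0.40 for histone chaperones. These values have no replicate error and were not tested.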

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

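All tests in this part were chosen only after the result was seen, except the test of free RNA for the interferon genes and the test of histone transcripts.

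Anti-PD-1 went with opposite directions in WT and KO tumours for 4 results, and none of these differences was tested, since each rests on 4 single libraries. Counted were results whose intervals excluded no change in both and, for gene lists, whose medians lay outside the middle 95% of random lists in both. The share of B cells was 1.23-fold in WT anti-PD-1 over WT IgG and 0.666-fold in KO anti-PD-1 over KO IgG, a difference of −0.89 on the log2 scale. With at least 1000 UMIs per cell the KO ratio was 0.838 (0.644 to 1.09), which includes 1. Chemokine genes in monocytes and macrophages had medians of −0.21 and 0.20, a difference of 0.41. Dissociation and heat-shock stress genes in tumour cells had medians of −0.21 and 0.54, a difference of 0.75. Hypoxia and glycolysis genes in tumour cells had medians of −0.37 and 0.34, a difference of 0.71. The WT stress median turned to 0.041 under the guard against free RNA, where the KO value was 0.15. The chemokine value in KO was −0.07 as a mean over cells and −0.05 in the monocyte-like cluster alone, so that its direction depended on the cells weighed. Plasmacytoid DCs, at 0.915-fold and 2.18-fold, and migratory DCs, at 0.894-fold and 1.37-fold, also lay on opposite sides, but the intervals of both WT ratios included 1.

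Neutrophils had a higher share in both KO libraries than in WT IgG as deposited. Debris in droplets stays open. With a higher minimum scaled to the depth of each library, the ratio of KO IgG to WT IgG was 1.43 (1.34 to 1.53). That minimum left 5041 of 5659 cells in WT IgG and 5243 of 5919 in KO IgG. Too few cells were removed to bring the ratio to 1, whichever cells were lost. An unscaled minimum of 1000 UMIs gave 0.866, so the ratio also depends on the scaling. A depth gap at the minimum of 500 UMIs is argued against by its direction. In KO IgG 18.9% of neutrophils held under 700 UMIs, against 7.09% of T cells, the next highest class with at least 50 cells. In WT IgG it was 3.15% of neutrophils. Losses at the minimum would therefore lower the neutrophil share of KO IgG and not raise it. Thinning each library by 1 fraction gave 1.42 (1.34 to 1.51). It could not decide alone, since it removed too few cells to bring the ratio below 1.31. Tumour genotype stays open, because with 1 library per group it cannot be told apart from any other difference between these mice or their digestion.

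Interferon-gamma response genes were lower in KO IgG in tumour cells and in monocytes and macrophages. A shallower library stays open. Each cell was thinned, to at most 1000 UMIs in monocytes and macrophages and to at most 3000 UMIs in tumour cells. The median went from −0.64 to −0.36 (−0.80 to −0.25) over 16 members in monocytes and macrophages. In tumour cells it went from −0.97 to −0.82 (−1.24 to −0.36) over 8 members. In both classes fewer members were left than without thinning. Thinning cannot decide, since it keeps the expected proportions of genes within each cell and mainly changes the weight of cells in the sum. Cells lost at the minimum depth were not addressed. Less free RNA is argued against because 11 of the 13 lower members lost more CPM in monocytes and macrophages than the class with the least of them held in WT IgG. That count did not allow for free RNA making up less of the CPM of classes with more UMIs per cell. Less interferon gamma in the lung is a candidate explanation, since Ifng over all cells of KO IgG was 0.219 (0.164 to 0.289) of WT IgG, on 60 and 358 UMIs. That library also had fewer T cells, and the step from Ifng to its targets was not tested.

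Hist1h1e, Slc15a2, Dmxl1, mt-Atp8 and Gm42418, singled out after their values were seen, were lower in KO anti-PD-1 across the classes where they were measured, though Dmxl1 and mt-Atp8 passed the limit in all but 1. A 2-fold loss of all histone transcripts that lack a poly(A) tail is argued against by their medians, the highest of which over 3 classes was −0.32. A smaller loss stays open. The median was negative in every measured class but tumour cells (0.23), and lowest in B cells at −0.99. These medians were not adjusted for proliferation, whose genes were higher in T cells and tumour cells of that library. In a test of free RNA, 5 of 5 genes lost more CPM in their highest class than the class with the least of them held. Free RNA makes up more of the CPM of cells with few UMIs, which the test ignored. The highest class of all but Gm42418 was B cells, with a median of 1615 UMIs in WT IgG against 11680.5 in tumour cells. Free RNA therefore stays open for those genes. It is argued against for Gm42418, which was highest in tumour cells and lost 4936 CPM there, against a least value of 388 CPM. A sequence variant of these mice or cells stays open for the 5 genes, since no reads were analysed here.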

How the results depend on the processing

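Alternatives with 700 or 1000 UMIs, libraries thinned by 1 fraction each, all CD8-led T cells, no neutrophils in the denominator, macrophage-like and monocyte-like clusters apart, ratios less the median, and ratios without the top cell were chosen after the data were seen. Values are against WT IgG unless another library is named, and the cause was not tested for any change in this part. Of the share ratios computed under alternatives, 724 stayed within their interval, 134 moved and 12 turned. With at least 500 detected genes, the share ratio was 2.64 in KO IgG and 1.70 in KO anti-PD-1 for tumour cells and 0.825 in KO IgG, 0.765 in WT anti-PD-1, 0.472 in KO anti-PD-1 and 0.617 in KO anti-PD-1 against WT anti-PD-1 for neutrophils. It was 1.60 in KO IgG and 2.06 in KO anti-PD-1 for monocytes and macrophages and 0.744 in KO IgG and 0.771 in KO anti-PD-1 for T cells. It was 1.15 in KO anti-PD-1 against WT anti-PD-1 for regulatory T cells. With at least 1000 UMIs per cell, the share ratio was 2.73 in KO IgG and 1.73 in KO anti-PD-1 for tumour cells and 0.866 in KO IgG, 0.730 in WT anti-PD-1, 0.460 in KO anti-PD-1 and 0.630 in KO anti-PD-1 against WT anti-PD-1 for neutrophils. It was 1.61 in KO IgG and 2.16 in KO anti-PD-1 for monocytes and macrophages and 0.719 in KO IgG and 0.742 in KO anti-PD-1 for T cells. It was 1.05 in KO anti-PD-1 against WT anti-PD-1 for regulatory T cells. With at least 700 UMIs per cell, the share ratio was 1.28 in KO IgG and 0.902 in KO anti-PD-1 for neutrophils and 1.75 in KO anti-PD-1 for monocytes and macrophages. Among cells other than neutrophils, the share ratio was 1.43 in KO IgG for monocytes and macrophages and 0.707 in KO IgG, 0.967 in WT anti-PD-1, 0.685 in KO anti-PD-1 and 0.969 in KO anti-PD-1 against KO IgG for T cells. With up to 20% mitochondrial UMIs, the share ratio was 0.682 in KO anti-PD-1 for T cells and 1.03 in KO anti-PD-1 against WT anti-PD-1 for regulatory T cells. With up to 5% mitochondrial UMIs, the share ratio was 0.565 in KO anti-PD-1 for T cells. With each library thinned by 1 fraction, the share ratio was 1.10 in KO anti-PD-1 against WT anti-PD-1 for regulatory T cells.

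Of the counts of genes at least 2-fold apart, 357 stayed within 1.5 times the reported count and 133 moved. A lower minimum admits more genes and a higher one fewer, by construction. With at least 1000 UMIs per cell, the gene count was 346 in KO anti-PD-1 for neutrophils. With cells thinned to 1000 UMIs, the gene count was 48 in KO IgG, 11 in WT anti-PD-1 and 31 in KO anti-PD-1 for tumour cells and 61 in KO IgG, 45 in WT anti-PD-1 and 90 in KO anti-PD-1 for monocytes and macrophages. It was 66 in KO IgG for T cells. With the minimum lowered to 10 UMIs per gene, the gene count was 1680 in KO IgG, 823 in WT anti-PD-1 and 1615 in KO anti-PD-1 for tumour cells and 755 in KO IgG, 580 in WT anti-PD-1 and 972 in KO anti-PD-1 for neutrophils. It was 587 in KO IgG, 514 in WT anti-PD-1 and 692 in KO anti-PD-1 for monocytes and macrophages and 687 in KO IgG, 506 in WT anti-PD-1 and 873 in KO anti-PD-1 for T cells. With the minimum raised to 200 UMIs per gene, the gene count was 171 in KO IgG, 21 in WT anti-PD-1 and 142 in KO anti-PD-1 for tumour cells and 23 in KO IgG, 5 in WT anti-PD-1 and 44 in KO anti-PD-1 for neutrophils. It was 27 in KO IgG, 18 in WT anti-PD-1 and 49 in KO anti-PD-1 for monocytes and macrophages and 11 in KO IgG, 12 in WT anti-PD-1 and 49 in KO anti-PD-1 for T cells. As a mean over cells of each cell's CPM, the gene count was 670 in WT anti-PD-1 and 929 in KO anti-PD-1 for tumour cells and 169 in KO IgG and 155 in WT anti-PD-1 for monocytes and macrophages. It was 115 in WT anti-PD-1 and 355 in KO anti-PD-1 for T cells. Under the guard against free RNA, the gene count was 64 in KO IgG, 18 in WT anti-PD-1 and 128 in KO anti-PD-1 for neutrophils and 43 in KO IgG, 30 in WT anti-PD-1 and 85 in KO anti-PD-1 for monocytes and macrophages. It was 65 in KO IgG, 43 in WT anti-PD-1 and 125 in KO anti-PD-1 for T cells.

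Of the list medians, 2711 stayed within their interval, 333 moved and 18 turned. With at least 500 detected genes, the median was −0.17 in KO anti-PD-1 against WT anti-PD-1 for suppressive genes in neutrophils and −0.24 in KO anti-PD-1 against WT anti-PD-1 for chemokine genes in neutrophils. With at least 1000 UMIs per cell, the median was −0.10 in KO anti-PD-1 against WT anti-PD-1 for suppressive genes in neutrophils and −0.069 in KO anti-PD-1 against WT anti-PD-1 for chemokine genes in neutrophils. With up to 5% mitochondrial UMIs, the median was 1.59 in KO anti-PD-1 for interferon-gamma genes in tumour cells. With cells thinned to 1000 UMIs, the median was 0.10 in WT anti-PD-1 for interferon-gamma genes in tumour cells and −0.17 in WT anti-PD-1 for histone chaperone genes in tumour cells. It was −0.035 in KO anti-PD-1 against WT anti-PD-1 for proliferation genes in tumour cells and −0.46 in WT anti-PD-1 for chemokine genes in tumour cells. It was −0.36 in KO IgG, 0.59 in WT anti-PD-1 and 0.12 in KO anti-PD-1 for interferon-gamma genes in monocytes and macrophages. With the minimum lowered to 5 UMIs per list member, the median was −0.21 in KO anti-PD-1 against WT anti-PD-1 for regulatory genes in NK cells. As a mean over cells of each cell's CPM, the median was −1.24 in KO IgG, 0.27 in WT anti-PD-1 and 0.33 in KO anti-PD-1 for interferon-gamma genes in tumour cells and −0.17 in KO anti-PD-1 for MHC class I genes in tumour cells. It was −0.017 in WT anti-PD-1 for histone chaperone genes in tumour cells and −0.15 in KO anti-PD-1 against WT anti-PD-1 and −0.012 in KO anti-PD-1 against KO IgG for proliferation genes in tumour cells. It was 0.11 in KO anti-PD-1 for interferon-gamma genes in monocytes and macrophages and −0.071 in KO anti-PD-1 against KO IgG for chemokine genes in monocytes and macrophages. Under the guard against free RNA, the median was 1.69 in WT anti-PD-1 for interferon-gamma genes in tumour cells and −0.50 in KO anti-PD-1 for MHC class I genes in tumour cells. It was 0.041 in WT anti-PD-1 for stress genes in tumour cells. In the monocyte-like cluster alone, the median was −0.0072 in WT anti-PD-1 for M1-type genes in monocytes and macrophages and 0.065 in WT anti-PD-1 and −0.17 in KO anti-PD-1 for interferon-gamma genes in monocytes and macrophages. It was −0.048 in KO anti-PD-1 against KO IgG for chemokine genes in monocytes and macrophages. In the macrophage-like clusters alone, the median was 1.02 in WT anti-PD-1 and 0.38 in KO anti-PD-1 for interferon-gamma genes in monocytes and macrophages. With TMM factors, the median was 0.45 in KO anti-PD-1 for cytotoxic genes in T cells. With median-of-ratios factors, the median was 0.47 in KO anti-PD-1 for cytotoxic genes in T cells. Less the median of all genes, the median was 0.49 in KO anti-PD-1 for cytotoxic genes in T cells.

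Of the ratios of named genes, 5434 stayed within their interval, 291 moved and 20 turned. With at least 500 detected genes, the log2 ratio was −1.19 in KO anti-PD-1 for Hba-a1 in T cells and −2.86 in KO anti-PD-1 for Hbb-bs in T cells. It was −1.39 in KO anti-PD-1 for Hbb-bs in neutrophils and 1.42 in WT anti-PD-1 for Hspa1b in neutrophils. With at least 1000 UMIs per cell, the log2 ratio was −1.14 in KO anti-PD-1 for Hba-a1 in T cells and −2.81 in KO anti-PD-1 for Hbb-bs in T cells. With up to 5% mitochondrial UMIs, the log2 ratio was −1.14 in KO anti-PD-1 for Hba-a1 in T cells and −2.81 in KO anti-PD-1 for Hbb-bs in T cells. It was 0.74 in WT anti-PD-1 for Hspa1b in neutrophils and 1.498 in KO anti-PD-1 and 0.86 in WT anti-PD-1 for Saa3 in tumour cells. With cells thinned to 1000 UMIs, the log2 ratio was 0.11 in KO IgG for Sgo1 in T cells and 0.077 in KO IgG for Pla2g16 in conventional DCs. It was −0.34 in KO anti-PD-1 and −0.69 in WT anti-PD-1 for Gzmb in monocytes and macrophages and −0.14 in WT anti-PD-1 for Iigp1 in tumour cells. Without the cell holding the most UMIs in each library, the log2 ratio was −2.07 in KO anti-PD-1 for Hbb-bs in T cells and −0.020 in KO IgG for Tnf in monocytes and macrophages. It was −1.37 in KO IgG for P2rx7 in neutrophils and 0.094 in KO anti-PD-1 for Saa3 in tumour cells.

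No paired analysis was possible because each group had 1 library and the labels pair none of them. Depth limits the share of neutrophils, since 66.0% of those in KO IgG and 78.3% in KO anti-PD-1 held under 1000 UMIs against 21.0% in WT IgG. With cells thinned to 1000 UMIs too few interferon-gamma genes were left for a median in tumour cells of KO IgG and of KO anti-PD-1 against WT IgG. The denominator of immune cells gives no value for tumour cells. The earlier rules for naming clusters were not run as alternatives.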

Other observations

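No test was made in this part, and what it names was singled out after the values were seen.

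Scgb1a1, the secretory protein of airway club cells, differed in nearly all classes at once, and club cells were not among the classes compared. It was lower in 9 of 9 classes of KO IgG, with a median log2 ratio of −3.25, and in 8 of 9 classes of WT anti-PD-1, with a median of −2.48. It was higher in 9 of 9 classes of KO anti-PD-1, with a median of 1.90. Ighg2b and Ighg1, which encode antibody heavy chains, were lower in 9 of 9 classes of KO IgG, with medians of −2.20 and −1.33. Plasma cells were 2.60% of cells in WT IgG and 1.72% in KO IgG. For all 3 genes, RNA free in the suspension was not told apart from expression within each class.

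Cxcl9 was higher in 4 of 5 classes of WT anti-PD-1, with a median of 1.48. Chil3, a marker of alveolar macrophages and monocytes, was higher in 5 of 6 classes of KO anti-PD-1, with a median of 1.91. Alveolar macrophages were 0.406% of cells in WT IgG and 0.822% in KO anti-PD-1. Free RNA was not told apart from expression here either. In migratory DCs, which carry antigen to lymph nodes, Il12b, which encodes a subunit of the cytokine IL-12, was 3.49-fold lower in KO IgG on 44 against 323 UMIs. In conventional DCs of WT anti-PD-1, Cxcl9 was 2.62-fold higher and Ccl17 2.02-fold lower. Plasmacytoid DCs were 0.671% of cells in WT IgG and 1.18% in KO anti-PD-1. Plasma cells were 2.60% in WT IgG and 1.27% in KO anti-PD-1.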
